A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

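The study comprised 6 arrays of Saccharomyces cerevisiae, 4 for expression and 2 for integration. Samples were grouped from their titles and genotype labels into fun30 deletion (2 arrays), wild type (2 arrays), the ISU1 cassette against the plasmid (1 array) and the SOD2 cassette against the plasmid (1 array). The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be chosen after seeing the data.

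Expression values are log2 signals per probe set, which the authors made with RMA before they were deposited. RMA corrects background, normalizes between arrays and summarises probes. This is per the submitters' processing notes, which also name limma. The versions and the covariates used by the authors are not given in the sources used here. RMA makes the arrays' distributions nearly equal, so a change of the whole transcriptome in one direction would not be seen. The table held 10928 probe sets. Of these, 5498 name 1 gene of the S. cerevisiae RefSeq table (assembly R64) and were tested, for 5449 genes, of which 47 have several probe sets. Another 1747 are annotated to a gene outside that table, 1 of them to several genes, and 3683 have no annotated gene. The 95th percentile of the probe sets annotated outside the table, a log2 signal of 5.24, served as the background level, and 5375 tested probe sets lay at or above it. A further mark is that 128 tested probe sets have names ending in _s_at or _x_at, which can cross-hybridise within gene families. No genome build is named by the array tables, so no coordinates are given and the RefSeq table was used for names and gene order.

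Integration values are linear ratios of the 2 channels of a barcode array, as deposited by the authors. Their scaling and direction are not given in the sources used here. Barcodes were amplified from genomic DNA with dye-labelled primers, per the labels. The plasmid pool carried Cy5 and the cassette pool Cy3 on the ISU1 array, and the reverse held on the SOD2 array. A rule fixed beforehand took arrays with r over 0.3 as oriented alike and turned 1 array for r under −0.3. The observed r was 0.53 over strains, so the deposited sign was kept on both. Array median ratios were 1.00 and 1.06. The table held 8120 features, with 158 empty on the ISU1 array and 42 on the SOD2 array. Feature numbers fall into blocks with an offset of 10971, and features at that offset named the same gene in all 3402 pairs where both are named, with 0 exceptions. They were taken as the 2 tags of a strain, and which tag is upstream is not given in the sources used here. This gave 4303 strains, 3841 with a gene name and 462 without. Both features were in the table for 3817 of them. Values from 1 feature are marked below only for some of the named strains. The log2 ratios were centred on the array median and averaged over a strain's features. The features of a strain correlated with r = 0.67 on the ISU1 array and 0.73 on the SOD2 array, and the SD of a feature was 0.28 on both. Deletion strains were named by the array annotation and the RefSeq table, with 3 gene IDs unmatched.

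Expression was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2 arrays against 2 with genotype alone, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 2 residual and 3.23 prior degrees of freedom. Lists were tested with camera at a preset correlation of 0.01 over 5449 genes and 34 lists, after averaging probe sets of a gene, with an estimated correlation and fry beside it. For integration, strains past 2-fold on both arrays were counted without a test. The mean over both arrays was tested against 0 with limma, which had 1 residual degree of freedom and an infinite prior, so that all strains shared a pooled variance. Lists on each array were described by the percentile of their median among 10000 random lists of the same size, for 17 lists. A plasmid pool shared by both arrays was simulated 100 times for unchanged strains, with the variance between strains beyond that of features divided equally between the plasmid pool and each cassette pool. No p-value was computed for a single integration array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.

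Named genes were FUN30, the 10 largest rises and 10 largest falls among those past the threshold with non-overlapping groups, and members of each list. From a list, all members past the threshold were named if at most 4, otherwise the 4 with the largest difference, and up to 2 where none passed. Named strains were the 10 highest and 10 lowest means with the same sign on both arrays, the strains at and beside the integration sites, up to 4 per list by the size of the mean, and the 3 with the largest difference between arrays in each direction. The procedures were tested on simulated data. With 200 of 5498 probe sets changed, limma recovered 63% of changes of 0.5 (log2) and 99% of changes of 1 with 8 false calls, and camera found the shifted list and 0 others. For the integration test on 4235 simulated strains, 197 of 200 strains shifted by 2 (log2) were recovered with 11 false calls. These simulations drew independent noise for each probe set, strain and array. False calls from correlated genes or from a shared plasmid pool could therefore not appear in them. For the integration test, shifts as small as the fun30 strain's mean of −1.32 were not simulated.

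The alternatives were the replicate number as a block, each array left out, another quantile normalization, median centring, dim probe sets left out, all probe sets tested, an intensity trend with a robust prior, other thresholds, and other list tests. For integration they were uncentred values, the first or second feature alone, equal spread, the ISU1 sign turned, extreme ratios left out, a robust prior, other fold sizes, and list means. Probe sets without an S. cerevisiae gene were left out of the main test because their gene is unnamed here.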

Results

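Gene expression was measured in log-phase cells of the haploid budding yeast strain BY4741 and of a mutant, which the labels call isogenic, deleted for FUN30, which encodes an ATP-dependent nucleosome remodeller of the Snf2 family. Each genotype had 2 arrays, grown in synthetic complete medium. The median log2 signal of the tested probe sets lay between 10.59 and 10.61 on all 4 arrays. The spread of the log2 difference between the arrays of a genotype was 0.14 (SD over probe sets) for the deletion and 0.18 for the wild type, against 0.24 to 0.37 between genotypes. In a separate experiment, a pool of homozygous diploid deletion strains was transformed with a URA3 cassette that replaces ISU1 or SOD2, or with the circular plasmid pRS416 as the control. The barcodes of the transformed pools were compared on 1 two-colour array for each cassette. The number of arrays limits the precision of both experiments. The labels do not say whether the replicate arrays came from separate cultures, so the p-values measure only the spread between these arrays.

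The targeted gene was examined first, on every array. FUN30 (YAL019W) had a log2 signal of 9.51 ± 0.16 (SD, n = 2) in the wild type and of 3.46 ± 0.13 (SD, n = 2) in the deletion. The measured difference of −6.05 ± 0.11 (SE) had an adjusted p of 5.46e-05 with limma. The deletion arrays lay below the background level of 5.24, which is the 95th percentile of probe sets for genes outside the S. cerevisiae gene table, so the size of the fall is only bounded. From the wild-type mean to that level it was at least 4.27 (log2). The neighbouring ORF ATS1 (YAL020C) rose by 0.54 (log2) with an adjusted p of 0.0317 (limma), and the other 8 measured neighbours of FUN30 did not pass. That rise was lost without fun30 deletion replicate 2 or without wild type replicate 1.

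In the fun30 deletion strain 75 probe sets rose and 71 fell among 5498 tested. The labels name no second isolate of either genotype. An effect of Fun30 loss therefore cannot be told apart from another difference between the strains, for these genes or for the lists below. MET17 and the chromosome IV run, described below, may be such differences. The largest fall after FUN30 was that of COS8, a member of a subtelomeric gene family, which was 5.44-fold lower. HO, the mating-type switching endonuclease, was 3.69-fold lower, and the G1 cyclin gene PCL1 was 3.48-fold lower. MET17, which encodes the sulphydrylase that makes homocysteine, was near background in the wild type and among the bright probe sets in the deletion. Of the 75 probe sets that rose, 39 belonged to a single run of neighbouring genes on chromosome IV.

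**Figure D1:**
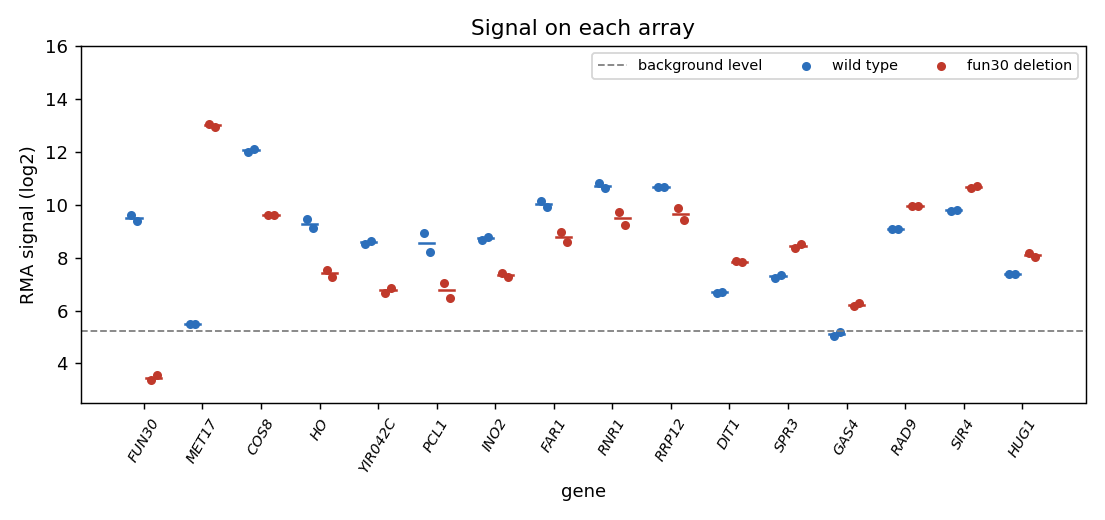
RMA signal (log2, vertical axis) of 16 named genes on the 2 wild-type arrays (blue) and the 2 fun30 deletion arrays (red); points are arrays, short bars are means of 2, and the dashed line is the background level of 5.24. FUN30 falls below background in the deletion, while MET17 goes from 5.48 to 12.99.

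The 10 largest falls apart from FUN30 were COS8, HO, YIR042C, PCL1, SCP1, INO2, ARR2, ARR3, IMD2 and FAR1. COS8 went from 12.06 to 9.62 (log2 difference −2.44 ± 0.07 SE, adjusted p = 0.000455, limma), and HO from 9.29 to 7.40 (−1.88 ± 0.15 SE, adjusted p = 0.00768, limma). The uncharacterised subtelomeric ORF YIR042C fell by 1.81, and SCP1, an actin-binding transgelin, fell by 1.58. INO2, an activator of phospholipid synthesis genes, was 2.64-fold lower. The arsenic resistance genes ARR2 and ARR3, which are neighbours, fell by 1.34 and 1.32. IMD2, an inosine monophosphate dehydrogenase gene, fell by 1.29, on a probe set whose name marks possible cross-hybridisation with its relatives. FAR1, which arrests cells in G1 in response to pheromone, fell by 1.26. PCL1 had the widest error of the set (−1.80 ± 0.28 SE, adjusted p = 0.0463, limma).

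The 10 largest rises were MET17, YAP6, YNR071C, DIT1, SPR3, CRF1, RMD5, AMD2, GAS4 and MFB1. MET17 had a measured rise of 7.51 ± 0.07 (SE, adjusted p = 3.66e-06, limma), from 5.48 ± 0.01 to 12.99 ± 0.08 (SD, n = 2 each). Its wild-type signal lay only 0.245 above the background level. The spore wall genes DIT1 and GAS4 and the sporulation septin gene SPR3 had measured rises of 1.16, 1.11 and 1.15. YNR071C, a putative aldose 1-epimerase near a chromosome end, rose by 1.23. GAS4 lay below the background level in the wild type, with a signal of 5.11. Its rise is therefore a bound of at least 0.988 (log2), and its place among the 10 largest rests on that wild-type signal. The other 5, YAP6, CRF1, RMD5, AMD2 and MFB1, rose by 1.08 to 1.26 and all lie in the chromosome IV run.

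The counts depended on single arrays. Without wild type replicate 1 there were 52 rises and 23 falls, without wild type replicate 2 there were 194 and 208, and without fun30 deletion replicate 1 there were 116 and 307.

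The run on chromosome IV comprised 47 consecutive measured probe sets from GCD6 (YDR211W) to EXG2 (YDR261C), in the gene order of the RefSeq table of assembly R64. All 47 had a positive difference, with a median of 0.85 (1.80-fold), and 39 passed the threshold. The run holds RAD9, the DNA damage checkpoint adaptor, which rose by 0.86 ± 0.06 (SE, adjusted p = 0.00686, limma). It also holds SIR4, a structural component of silent chromatin, which rose by 0.88 ± 0.06 (SE, adjusted p = 0.00686, limma), and the chaperone genes AHA1 and HSP78, which rose by 0.87 and 0.79. The histone genes HTA1 and HTB1 lie inside the run and differed by only 0.06 and 0.05, which did not pass. Their signals were among the highest of the run, from 14.08 to 14.38 (log2), where the highest signals of the arrays were 15.18 to 15.21. Whether signals this bright can still show a rise of the run's size was not tested. Of the 20 nearest measured probe sets outside the run, 10 on each side, the median difference was 0.05. The run was delimited after the values were seen, as the stretch with the highest sum of differences, each less 0.4 (log2). With its probe sets left out of the fit, a setting chosen after seeing the data, 23 probe sets rose and 45 fell.

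**Figure D2:**
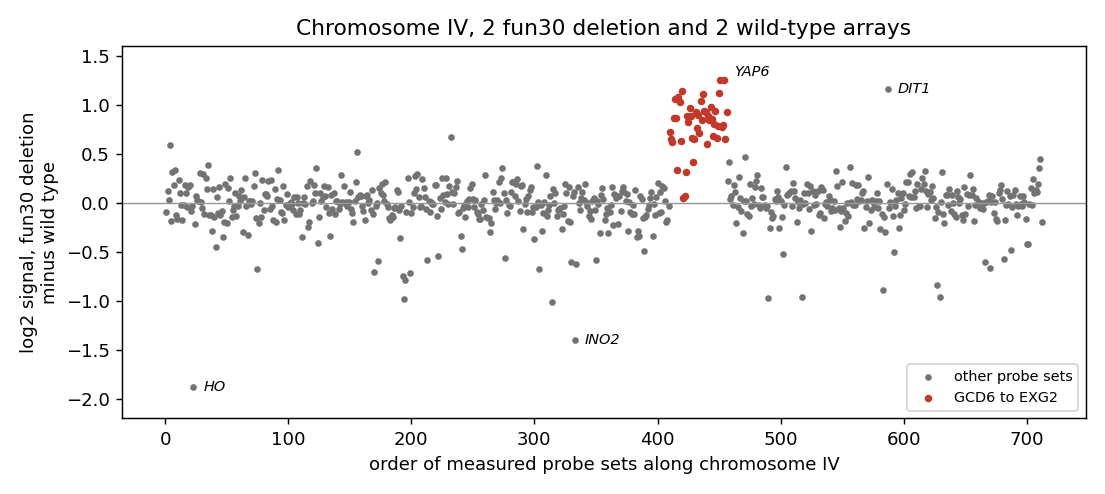
Difference in log2 signal between the fun30 deletion and the wild type (vertical axis, means of 2 arrays each) for every measured probe set of chromosome IV in gene order (horizontal axis); red points are the 47 probe sets from GCD6 to EXG2. The red points have a median of 0.85, and their neighbours on both sides lie near 0.

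Genes of DNA repair, the process the study addresses, were compared as lists fixed beforehand. None of the 10 measured genes of homologous recombination (RAD52 group) and none of the 9 measured genes of end resection other than FUN30 passed the threshold, over all genes or adjusted over the list alone, with 1 and 2 genes at an unadjusted p under 0.05 in limma. The largest differences were −0.22 for PSY3 and 0.15 for RAD59 in the first list, and 0.37 for XRS2 and −0.19 for MRE11 in the second. In non-homologous end joining, 1 of 6 genes rose, also 1 adjusted over the list alone. This was DNL4, the DNA ligase of that pathway (0.54 ± 0.08 SE, adjusted p = 0.0367, limma), and the call was lost without fun30 deletion replicate 2 or wild type replicate 1. In the DNA damage checkpoint list, RAD9 was the 1 gene of 13 that rose, also adjusted over the list alone. No gene of the anti-recombinases and helicases (10 measured), of mismatch repair (5) or of the nucleosome remodellers other than FUN30 (29) passed over all genes, with 4, 1 and 2 genes at an unadjusted p under 0.05 in limma. Adjusted over the list alone, 1 helicase list gene fell and 1 mismatch repair gene rose. The largest differences there were −0.36 for ELG1, −0.23 for PIF1, 0.37 for MLH2, 0.16 for MLH3, −0.24 for RSC2 and 0.23 for INO80. Of the 19 DNA damage induced genes, HUG1, a ribonucleotide reductase inhibitor, rose by 0.72 ± 0.07 (SE, adjusted p = 0.0145, limma). The large reductase subunit RNR1 fell by 1.23 ± 0.18 (SE, adjusted p = 0.0367, limma), and the counts adjusted over the list alone were the same.

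The lists of ribosome biogenesis and of G1/S and S phase cyclic genes were lower in the deletion by camera with the preset correlation, but not with an estimated correlation. The estimate rests on 2 residual degrees of freedom, and 0 of the 34 lists had an unadjusted p under 0.05 with it (camera). It has too little power to tell the lists apart, here and for the lists below. The preset correlation of 0.01 takes the genes of a list as nearly independent. Its p-values are too small where genes move together between arrays of a genotype. The fry test gave adjusted p = 0.277 for ribosome biogenesis and 0.280 for the G1/S list. Of the 9 lists that camera called with the preset correlation, fry called only the COS family and Y' helicases. In ribosome biogenesis, 49 of 50 measured genes had a lower mean in the deletion, with a median difference of −0.43, and 5 fell over all genes against 28 adjusted over the list alone. Among these were the rRNA processing genes RRP12 (−1.02), UTP13 (−1.01) and UTP4 (−0.97), and MAK16 (−0.95), needed for the large subunit. The camera test gave the list an adjusted p of 1.58e-15 with the preset correlation, and adjusted p = 0.899 with an estimated correlation. The list's median difference ranged from −0.17 to −0.70 over the 4 pairings of a deletion with a wild-type array, and the arrays within a genotype differed by 0.30 in the deletion and 0.22 in the wild type. In the list of G1/S and S phase cyclic genes, PCL1 and RNR1 fell among 23, against 9 adjusted over the list alone (camera adjusted p = 1.84e-05, and adjusted p = 0.899 with an estimated correlation). This list's median difference ranged from −0.128 to −0.546 over the 4 pairings. The arrays within a genotype differed by 0.161 in the deletion and 0.195 in the wild type. The single-gene calls of UTP4, UTP13, MAK16, RRP12, PCL1, RNR1 and FAR1 were lost without wild type replicate 1, and that of RRP12 also without wild type replicate 2. The cytosolic ribosomal proteins did not move as a list (camera adjusted p = 0.552, 0 of 68 passed either way and 2 at an unadjusted p under 0.05 in limma). Their largest differences were −0.28 for RPS27A and −0.21 for RPS9A, the latter with an unadjusted p of 0.243 (limma).

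The COS family and Y' helicase list had 8 measured members, of which COS8 and COS12 (−1.11) fell, against 3 adjusted over the list alone (camera adjusted p = 0.00441, and adjusted p = 0.899 with an estimated correlation). In the sporulation and meiosis list, 4 of 42 genes rose, 5 adjusted over the list alone, and 1 fell by either count (camera adjusted p = 0.0362, and adjusted p = 0.899 with an estimated correlation). DIT1 and SPR3 rose most, SPO1, a phospholipase-like gene of meiosis, rose by 0.71, and SSP1, a gene of spore membrane growth, fell by 0.78. The general stress response list was higher, with positive differences in 36 of 40 genes and a median of 0.16 (camera adjusted p = 0.00037, and adjusted p = 0.899 with an estimated correlation). Its 1 gene that rose by either count was HSP78, which lies in the chromosome IV run. Without wild type replicate 1 the adjusted p of this list was 0.779, and the wild-type arrays themselves differed by −0.20 in its median (replicate 1 minus replicate 2).

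Another 4 lists were lower by camera with the preset correlation, each with an adjusted p of 0.0384. They were the GCN4 targets, ergosterol synthesis, the zinc regulon and the a-specific genes. With an estimated correlation their adjusted p was 0.931 for the GCN4 targets and 0.899 for the other lists. Single members rarely passed. LYS4 rose by 0.65 and lies in the chromosome IV run, against the direction of the GCN4 list, whose median was −0.10. VEL1, a gene of unknown function near a chromosome end, passed in the zinc list with a difference of −0.62, but the mean signals of both genotypes lay below the background level. No ergosterol or a-specific gene passed, with 8 and 3 genes at an unadjusted p under 0.05 in limma, and the largest differences were −0.54 for ERG5, −0.40 for ERG3, −0.36 for BAR1 and −0.25 for AGA2. Adjusted over the list alone the counts were the same. Without wild type replicate 1 none of these 4 lists passed, with adjusted p values of 0.869, 0.319, 0.442 and 0.0886. Without fun30 deletion replicate 1 the GCN4, ergosterol and zinc lists had adjusted p values of 0.286, 0.0516 and 0.129, and without fun30 deletion replicate 2 the ergosterol list had 0.0602. The a-specific list passed in no fit that left out 1 array, with adjusted p values from 0.0516 to 0.162. The zinc list also did not pass with dim probe sets left out (adjusted p = 0.0976).

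The other lists, 25 in all with those of DNA repair, ribosomal proteins and the FUN30 neighbours, had camera adjusted p values from 0.0629 to 0.993. Among the haploid-specific genes HO and FAR1 fell of 13 (3 adjusted over the list alone). Among the silent mating-type and alpha-specific genes STE3, the a-factor receptor gene, rose by 0.48 (1 of 7 by either count), and SIR4 was the 1 silencing factor of 13 that rose, while 3 fell adjusted over the list alone. Of 26 sulphur and methionine genes, MET17 and MET28 (0.48) rose, and adjusted over the list alone 3 rose and 2 fell. MET17 was also the 1 of the 4 BY4741 auxotrophic markers that rose by either count. In the phosphate list of 16, PHO89 (0.69) and SPL2 (0.53) rose and PHO11 (−0.54) fell, with 3 and 1 adjusted over the list alone. In the iron regulon of 29, HMX1 rose by 0.73 and FRE1 fell by 0.92, with 6 and 3 adjusted over the list alone. The G2/M and M/G1 list of 25 had SCW11 (0.57) up and FAR1 down, with 9 and 7 adjusted over the list alone. Single genes rose in the pheromone response (PRM5, 0.59), heat shock (AHA1), glycolysis and fermentation (ADH2, 0.52), hexose transport (HXT2, 0.63) and PAU lists (TIR1, 0.59). Adjusted over the list alone the counts were 1, 1 and 1 in the first 3 of these, 2 up and 1 down in hexose transport, and 4 up and 3 down in the PAU list. No gene of the histone list (9 measured) or of the respiratory chain (37 measured) passed by either count, with 0 genes at an unadjusted p under 0.05 in limma, and their largest differences were −0.16 for HHO1, −0.11 for HTZ1, 0.23 for SDH1 and 0.21 for CYC7. Without wild type replicate 1 the single-gene calls of SPO1, HSP78, VEL1, STE3, MET28, SPL2, PHO11, FRE1, SCW11, ADH2 and HXT2 were lost. Those of STE3 and SPL2 were also lost without fun30 deletion replicate 2, that of MET28 without fun30 deletion replicate 1, and that of PHO11 without wild type replicate 2.

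The integration arrays addressed which deletions alter the integration of a linear cassette by its homologous ends, relative to transformation by a circular plasmid. The sources used here do not say which pool is the numerator of the deposited ratio, so strains are described as above or below the array median. Strains lacking a recombination gene of the RAD52 group lay high on both arrays, and strains lacking FUN30 or the resection factors EXO1 and SGS1 lay low on both. The RAD52 group had all 9 measured strains above the median on each array, with a list median of 1.47 (log2) on the ISU1 array and 1.25 on the SOD2 array. The fun30 strain lay at −1.43 and −1.20, exo1 at −1.31 and −1.33, and sgs1 at −1.29 and −0.86. The fun30 values came from 1 feature on each array, and the sgs1 value on the ISU1 array from 1 feature. There was 1 array for each cassette, so no value of a single array has a replicate.

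Over 4235 strains with a value on both arrays, the log2 ratios correlated with Pearson r = 0.53 and Spearman rho = 0.38, across strains, which are not independent replicates. The plasmid pool may be the same on both arrays. Unchanged strains sharing a plasmid pool gave a simulated r of 0.42, and the observed covariance was 0.135 against a simulated 0.108. On both arrays 81 strains lay at least 2-fold above the median and 27 at least 2-fold below it. Independent arrays would give 6.30 and 1.08 strains, and the simulated shared pool gave 14.2 and 13.8. The simulated values depend on the equal division of variance and on symmetric normal log2 ratios, both of which were assumed. A larger shared part was not simulated, so the excess over these values does not exclude a shared pool as its source. In the limma test of the mean over both arrays, 255 strains lay above and 115 below. That test takes the arrays as independent, which a shared pool breaks, and uses the same error of 0.246 (SE) for every strain.

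**Figure D3:**
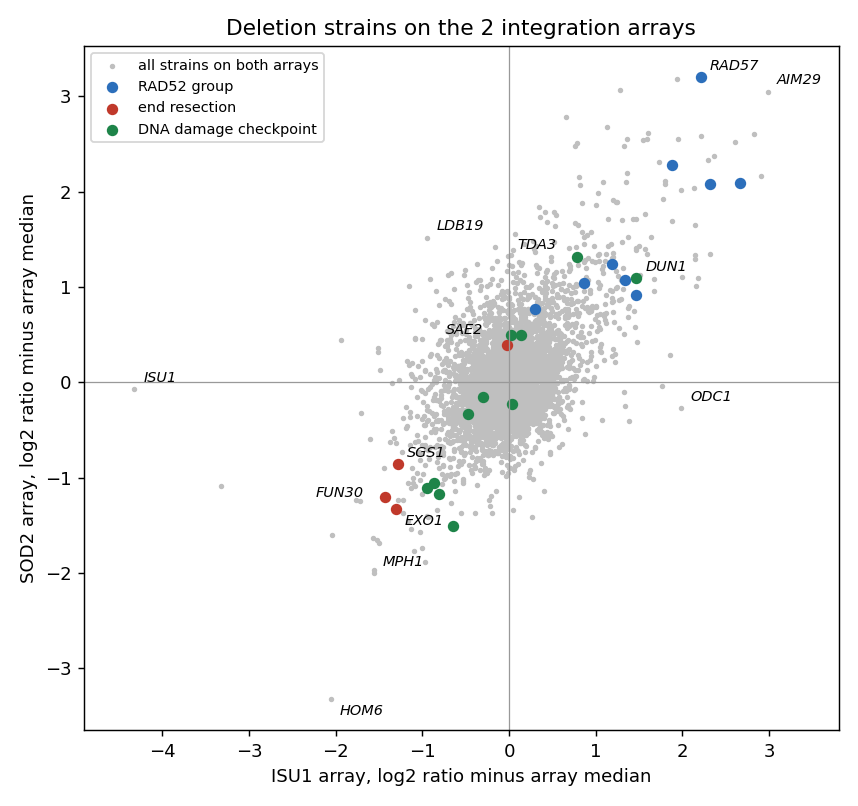
Log2 ratio of each deletion strain minus the array median on the ISU1 array (horizontal axis) and the SOD2 array (vertical axis), for 4235 strains (grey); larger points are strains of 3 gene lists, and labels name single strains. RAD52 group strains lie in the upper right, and FUN30, EXO1 and SGS1 in the lower left.

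The 10 highest strains were deleted for AIM29, KRE1, RAD57, NUP188, BUD27, SAW1, PPR1, RAD59, a gene whose tags are unnamed in the array table, and NUP170. The aim29 strain had the highest mean, 3.02 (adjusted p = 3.09e-30, limma), followed by kre1 (2.72), which lacks a cell wall glucan protein, and rad57 (2.71). The nup188 (2.56) and nup170 (2.32) strains lack nuclear pore proteins. PPR1 activates the pyrimidine synthesis genes, and its strain had a mean of 2.40. The bud27 strain had a mean of 2.56, saw1 2.54 and rad59 2.38. The nup188, bud27 and saw1 values came from 1 feature on each array. The unnamed strain had a mean of 2.37. The 10 lowest were HOM6, CDC26, ISU1, MET22, MPH1, NUM1, COX6, LDH1, SSN2 and SSN3. The hom6 strain, which lacks homoserine dehydrogenase, had a mean of −2.69 (adjusted p = 2.28e-24, limma). The mph1 strain lacks a DNA helicase and had a mean of −1.78 (adjusted p = 7.01e-11, limma). The met22 strain had a mean of −1.82, num1 −1.77, cox6 −1.60, ldh1 −1.59 and ssn2 −1.59, and ssn3 lay at −1.77 and −1.24 on the ISU1 and SOD2 arrays. The cdc26 value on the ISU1 array, −3.32, came from 1 feature, against −1.09 on the SOD2 array. The limma calls of cdc26 and isu1 were lost with a robust prior.

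In the RAD52 group, 8 of 9 strains lay above the median in the limma test, and all 9 adjusted over the list alone. Besides rad57 and rad59, rad55 had a mean of 2.20 and rad54 of 2.08. The rad54 values came from 1 feature on each array, and the rad55 value on the SOD2 array from 1 feature. In the end resection list, fun30 (−1.32, adjusted p = 4.90e-06), exo1 (−1.32, adjusted p = 5.08e-06) and sgs1 (−1.07, adjusted p = 0.0004) lay below, all by limma and also adjusted over the list alone. The sae2 strain lay at −0.02 and 0.40, and xrs2 at 0.94 on the ISU1 array, with no value on the other. The list's median was lower than that of nearly all random lists, at percentile 0.00 on the ISU1 array and 0.01 on the SOD2 array. Without the fun30 strain, a setting chosen after seeing the data, these percentiles were 0.23 and 0.14.

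The DNA damage checkpoint strains went both ways, with 2 above and 4 below, by limma and also adjusted over the list alone. The dun1 (1.28) and rad9 (1.05) strains lay above. The 4 below lack the checkpoint clamp or its loader, ddc1 at −1.07, rad24 at −1.03, rad17 at −0.99 and mec3 at −0.96. Their list had percentile 1.61 on the ISU1 array and 3.21 on the SOD2 array. The first of these lay inside the central 95% with the first feature alone (5.53), with the second alone (3.95) and with list means (14.97). In the list of nucleotide and base excision repair, 4 strains lay above by either count, rad1 (1.90) and rad10 (2.00), which lack the subunits of a flap nuclease, saw1, and apn1 (0.84). The slx4 strain (1.83), from the anti-recombinase and helicase list, lay above with elg1 (0.96) and rrm3 (0.83), and mph1 below, by either count. In mismatch repair, msh3 (1.47) was the 1 strain above by either count, and msh6 (−0.43), pms1 (−0.46) and mlh2 (−0.29) did not pass.

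Of 19 nucleosome remodeller strains other than fun30, 4 lay above, rsc1 (1.91), rsc2 (0.92), isw1 (0.92) and swr1 (0.77), against 5 above and 1 below adjusted over the list alone. The list's percentile was 99.98 on the SOD2 array and 69.8 on the ISU1 array. Oxidant defence strains had percentiles 0.10 on the ISU1 array and 0.55 on the SOD2 array, where 7 of 17 lay above the median. The SOD2 placement was lost with the first feature alone (21.7) and with list means (6.78). By limma, hyr1 (−0.89) and skn7 (−0.82) lay below, against 3 adjusted over the list alone, while tsa1 (−0.67) and ccs1 (−0.58) did not pass over all strains. In the RAD6 pathway list 4 strains lay above and 1 below, against 5 and 2 adjusted over the list alone. Those above included mms1 (1.72) and the chromatin assembly strains cac2 (1.44) and rlf2 (0.72), and hir1 (−0.85) lay below. The mms1 strain lay at 0.66 on the ISU1 array and at 2.78, from 1 feature, on the SOD2 array. The list had percentile 98.95 on the SOD2 array, 85.0 with the first feature alone, and 67.3 on the ISU1 array, 99.1 with the first feature alone. Strains of transformation and endocytosis had percentiles 99.92 on the SOD2 array and 96.8 on the ISU1 array, with arp1 (0.72) and rvs161 (0.71) above by either count, and pmr1 (0.54) and spf1 (0.43) not past the threshold. With the first feature alone the SOD2 median of that list was −0.02 (percentile 47.1) and the ISU1 percentile was 99.0, and with list means the SOD2 percentile was 95.7. The anti-recombinase list had percentiles 95.39 and 99.39 on the ISU1 and SOD2 arrays, and the second lay inside the central 95% with the second feature alone (92.6) and with list means (93.7).

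The remaining lists lay within the central 95% of random lists on both arrays by their medians. By list means, excision repair lay outside on both arrays (99.9 and 99.1) and pyrimidine supply on the SOD2 array (99.8). With the second feature alone pyrimidine supply lay outside on the ISU1 array (1.20). In pyrimidine supply, ppr1 and ura7 (1.59) lay above and ura4 (−0.75) below by either count, and urh1 (−0.43) did not pass. The ura4 strain lay below the median on the ISU1 array alone (−1.94, and 0.44 on the SOD2 array, 1 feature each), and its call was lost with uncentred values, with the second feature alone and with a robust prior. In the kinetochore list, gim4 (1.58) and lrs4 (0.76) lay above, and mcm16 (−0.70) and mcm21 (−0.67) passed only adjusted over the list alone. The histone list had htz1 (0.77) above and hhf1 (−0.77) below by either count, and hht1 (−0.58) and hht2 (−0.42) did not pass. By limma no strain passed by either count in the next 3 lists, with 0, 1 and 2 strains at an unadjusted p under 0.05. These were end joining (yku70 0.22, yku80 0.22, lif1 0.25 and dnl4 −0.22), the silencing factors (sas2 −0.49, dot1 0.38, esc1 0.25 and sas5 −0.22) and iron-sulphur cluster assembly (nfu1 −0.58, isa1 −0.52, isu2 −0.24 and isa2 0.22).

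Some of the strains deleted at or beside the integration sites differed between the arrays. The isu1 strain lay at −4.32 on the ISU1 array, from 1 feature, and at −0.07 on the SOD2 array. The odc1 strain, deleted for the ORF beside ISU1, lay at 1.99 on the ISU1 array and −0.27 on the SOD2 array. The tda3 strain, from the SOD2 region, lay at −0.01 on the ISU1 array and 1.32 on the SOD2 array. The sod2 strain lay at −0.51 on the ISU1 array and had no value on the SOD2 array. The other strains of these regions were gip3 (mean 0.90), rds2 (0.28), cox11 (−0.38), spp1 (−0.11), stp2 (0.10) and rpl27a (0.49). Of these, gip3 (1.10 on the ISU1 array and 0.69 on the SOD2 array), cox11 (−0.56 and −0.21) and spp1 (−0.17 and −0.05) lay on the same side of both. The rds2, stp2 and rpl27a strains lay on opposite sides. In the limma test 2 of the 9 strains with both values lay above and 1 below, against 3 and 1 adjusted over the list alone. The calls over all strains were odc1 and gip3 above and isu1 below. The odc1 call was lost with either feature alone, with uncentred values and with a robust prior. Over all strains, the 3 that were lower on the ISU1 array by the most were isu1, ldb19 (−0.94 on the ISU1 array and 1.52 on the SOD2 array) and ura4 (−1.94 and 0.44). The 3 that were higher by the most were odc1, pho86 (1.77 and −0.04) and rpl27a (1.38 and −0.41). None of the differences between cassettes was tested.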

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

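The tests of the ratio's direction, of the cassette's own tag and of the odc1 features below were chosen only after the result was seen. That of a single bad feature for isu1 was chosen after the pattern was seen, but before its own result was. Differences between the 2 integration arrays were not tested, since each cassette has 1 array.

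On the integration arrays, 13 named strains lay on opposite sides of the median. Expressed as the ISU1 array minus the SOD2 array (log2), these were ODC1 at 2.25, PHO86 at 1.81, RPL27A at 1.78, RDS2 at 0.75, LDB19 at −2.46, URA4 at −2.39, CCS1 at −1.87, TDA3 at −1.33, ISA2 at −0.61, SAS5 at −0.51, ISU2 at −0.51, SAE2 at −0.42 and STP2 at −0.22. List medians had opposite signs for pyrimidine supply (−0.39), excision repair (0.13) and the kinetochore list (−0.079). In data outside the comparisons, 3 probe sets with no S. cerevisiae gene name passed the threshold when all probe sets were tested with limma. All 3 were lower in the fun30 deletion, with log2 differences of −1.53, −0.72 and, for the reporter control RPTR-Sc-J01347-4_at, −0.53.

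The isu1 strain at −4.32 and the odc1 strain at 1.99, both on the ISU1 array alone, form a pattern at the integration site. For odc1 a single bad feature is argued against by its pair of features on that array, the lower of which lay at 1.96. For isu1 it stays open: 0 of 7502 feature pairs within arrays (0.0%) differed by 4.25, its gap between arrays, but its own value has no second feature. A candidate explanation is that the deposited ratio is the plasmid pool over the cassette pool. A strain that lacks sequence beside the target, or a recombination gene, would then lie high, and the lower of the 2 array medians of the RAD52 group was 1.25. Whether the cassette carried the tag of its own deletion strain into every transformant, which could also put isu1 at the bottom of its array, stays open, because the sod2 strain had values for 0 features on the SOD2 array.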

How the results depend on the processing

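The alternatives that leave out the chromosome IV run or the fun30 strain were chosen only after the result was seen. FUN30 stayed lower and past the threshold under every expression alternative run. Without 1 array, rises ranged from 52 to 194, falls from 23 to 307, and lists past the threshold from 4 to 11. Fewer arrays enter those fits, the lone array being assumed to vary like the other group. The lowest values of all 3 came without wild type replicate 1, where 49 of the 52 rises and 22 of the 23 falls were shared with the main result. Without the chromosome IV run, which removes 39 rises, 23 rose and 45 fell. At an adjusted p threshold of 0.1 there were 132 rises and 196 falls. With the replicate number as a block, 271 rose and 523 fell; same-numbered arrays deviated together with a correlation of 0.257 over only 2 pairs, so the numbers are not taken as pairing. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05). The fry test, which tests direction without comparing with other genes, called 4. Of these, COS family and Y' helicases was the 1 list that camera had also called with the preset correlation. The others were the auxotrophic markers, which hold MET17 (fry adjusted p = 0.0225), the silent mating-type and alpha-specific genes (0.0317) and the DNA damage induced genes (0.0347). Over the 4 pairings of a deletion with a wild-type array, the median difference was 0.129 to 0.175 for the silent mating-type and alpha-specific list. For the DNA damage induced list it was 0.088 to 0.100. The other splits of the 4 arrays are too few for a share under 0.05, with 146 calls for the real split and 0 for the highest other (35 at an unadjusted p, limma). For integration, turning the ISU1 sign gave r = −0.53, 1 strain past 2-fold on both arrays and 0 limma calls (20 at an unadjusted p). The first feature alone gave r = 0.40 and 207 limma calls, and uncentred values gave 241; the cause was not tested. At 1.5-fold 307 strains passed on both arrays and at 3-fold 25, by construction of the rule. Of the 11 placements of gene lists outside the central 95% on an integration array, 6 were kept in every alternative that gave a value, the turned sign aside. They were those of the RAD52 group and end resection on both arrays, of oxidant defence on the ISU1 array and of the remodellers on the SOD2 array. The other 5 were lost in at least 1, among the first feature alone, the second alone and list means; the cause was not tested. End resection had too few strains on the ISU1 array for a value with the second feature alone. The stp2 mean, not past the threshold, changed sign to −0.031 with the second feature. Of 699 values of the 70 named genes under alternatives, 644 kept direction and side of the threshold, 43 lost the threshold, 12 gained it and 0 changed direction. For 89 named strains these were 458, 39, 9 and 1 of 507. Signal over background limits MET17 and GAS4 in the wild type, FUN30 in the deletion, and VEL1.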

Other observations

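All groups in the first paragraph were chosen after their values were seen. Tests below on a second copy, on Fun30 itself and on MET17 were also chosen only after the result was seen. So were those on the concentration at chromosome ends, with and without the largest falls. Those on chance clustering, normalization and shared probe sets were chosen after the patterns were seen, but before their own results were.

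The deletion strains of some subunits of the same complex lay on the same side of both integration arrays. These subunits were picked for their values, other subunits were not tallied, and no enrichment was tested. Of the Mediator kinase module, ssn2 (mean −1.59), ssn8 (mean −1.12) and ssn3 (−1.77 and −1.24) lay below by limma, and srb8 at −1.35 and −0.01 did not pass. The strains lacking the deubiquitinase Ubp3 (−1.26) or its cofactor Bre5 (−1.33) lay below. Strains lacking an N-terminal acetyltransferase subunit lay above, ard1 at 2.05, nat1 at 0.88 and mdm20 at 2.11. So did 3 of the RSC remodeller, ldb7 at 2.25, rsc1 at 1.91 and rsc2 at 0.92, and of the Gtr GTPases, gtr2 at 2.09 and gtr1 at 1.15. In chromatin assembly factor 1, msi1 (0.71) lay above with cac2 and rlf2.

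Genes that fell in the fun30 deletion were tested for concentration at chromosome ends, as a hypothesis raised by COS8, YIR042C and ARR3. Of the 10 outermost measured genes of each arm, 20 of 320 fell (6.25%), against 50 of 5178 elsewhere (0.97%, FUN30 not counted as fallen), an odds ratio of 6.84 (Fisher's exact test, p = 1.25e-09, across genes, which are not independent). These lay on 14 arms and included GEX1 (−0.80), YER187W (−1.01), YFL065C (−0.85), AIF1 (−0.65) and AYT1 (−0.62). Without _s_at and _x_at probe sets, such as those of GEX1 and YFL065C, the fallen end genes lay on 8 arms. Without probe sets named _s_at or _x_at the odds ratio was 4.42 (11 of 263 against 50 of 5107, exact p = 0.000148), which argues against shared probe sets as the whole source. Since the largest falls raised the hypothesis, the test was repeated without the 10 largest. The odds ratio was then 5.70 (15 of 315 against 45 of 5173, exact p = 8.73e-07), and 3.12 without the _s_at and _x_at probe sets as well (7 of 259 against 45 of 5102, exact p = 0.0118). Those 7 lay on 5 arms. Fun30 may keep some genes near chromosome ends expressed, but a difference in the chromosome ends of the strains would look the same and was not tested. The strains also differed in the chromosome IV run, which holds the silent chromatin gene SIR4 (0.88). Whether that rise affects end genes was not tested, so a role of Fun30 cannot be told apart from it. Outside the chromosome IV run, 5 end genes rose (odds ratio 2.61, exact p = 0.0571).

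The chromosome IV run is too long for chance clustering, since 0 of 1000 shuffles of gene order reached its highest 11-gene running median of 0.89. Genes of like signal outside the run had a median difference of −0.007. RMA makes the arrays' distributions nearly equal, so a value near 0 was likely whatever the cause of the run. It shows only that genes of like signal were not shifted as a group, and does not decide on the normalization between arrays. A second copy of the segment in the deletion strain may account for the run. In the run 91.5% of probe sets were up by 0.4 or more, and so was 1 of the 20 flanking ones, the transposon ORF YDR261C-D (0.42). The run was drawn by a search with that same step of 0.4, which largely set both shares. They therefore cannot decide for or against a second copy. An effect of Fun30 loss on the segment cannot be told apart from it, since both deletion arrays show the run (0.84 in the lower) and the labels name no second isolate.

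MET17 had a measured difference of 7.51 while the highest of the other 25 sulphur genes, MET32, lay at 0.66 and in the chromosome IV run, which argues against joint induction of the pathway. A swap of arrays between genotypes is argued against by FUN30, for which the smallest gap between a wild-type and a deletion array was 5.85. The wild-type signal lay 0.245 above background (log2), as it would if the gene were absent there, and BY4741 is known to lack it under its other name, MET15. A candidate explanation is that the deletion strain carries a MET17 copy and so differs from the wild type at more than FUN30. Loss of Fun30 cannot induce a gene that the parent strain lacks. With BY4741 as the parent, Fun30 loss alone would therefore not account for this rise. The presence of the gene in either strain was not tested.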
